A study of Homo sapiens with 8 samples.

How the data were processed

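RNA was sequenced from CD8+ T cells sorted by flow cytometry from the peripheral blood of 8 patients, 4 with lung cancer and 4 with melanoma, 1 library per patient. Per the labels' protocols, the libraries were made with a kit that reads the 3' end of polyadenylated RNA and were run on an Illumina MiniSeq. Per the submitters' processing notes, the tools were HISAT2 and StringTie and the genome build was GRCh38. Versions, roles of the tools, the gene annotation, trimming and any filter on genes are not given in the sources used here. The authors deposited 1 table of TPM values, in which a gene's reads are divided by a transcript length and scaled within the library. The table held 24530 gene names, none repeated, with 8 columns that were matched to the samples by their sample number.

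TPM keeps no read count, so the depth of each library is unknown and no counting interval can be given. The deposited TPM columns summed to between 545804 and 706589, below 1000000, so the table holds part of each library. Reads that come from the 3' end do not grow in number with transcript length, and division by length therefore raises short genes against long ones within a library. This division by itself leaves ratios of a gene between libraries as they are, as long as the same length was used in each. The scaling within the library can change them, since a load of short transcripts in a library lowers its other genes. The short transfer RNA gene MT-TF took 8.35% of the TPM total in melanoma sample 2 and 0.926% in melanoma sample 1. The number of genes above 0 stood in for depth and ran from 8457 to 20296. Of 61 respiratory chain, glycolytic and ribosomal protein genes, 4 were listed at 0 in lung cancer sample 1, 3 in melanoma sample 1 and 3 in melanoma sample 3. A value of 0 is therefore given as "listed at 0". Some genes with such values are given library by library, and others by their log2 difference alone.

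Values were analysed as log2(TPM + 1), and every fold change is on that scale, which understates the change of low genes. Genes with a TPM of at least 1 in at least 4 of the 8 samples were tested, which left 9105. Sex-linked genes whose level differs between the sexes, 87 in all, were left out of every gene test, list score and distance. They were still counted in the TPM totals of the samples and in the number of genes above 0. Melanoma was compared with lung cancer by limma 3.58.1 (R 4.3.3) with eBayes using a mean-variance trend and robust variances, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels name no batch, so the model had no covariate. Replicate numbers follow the order of deposit and pair no samples. Each library came from a separate patient, as the labels give it. The p-values measure the spread between patients together with that between libraries, since 1 library per patient cannot separate them.

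The comparisons, the tests and 27 gene lists were fixed before the data were examined. The lists cover CD8+ T cell states, cell functions, and markers of other cells that blood or the tumours could bring in. Lists with at least 4 tested members, 21 in all, were tested by camera in limma with a preset inter-gene correlation of 0.01, by camera with an estimated correlation, and by fry. The score of a list in a sample was the mean log2(TPM + 1) of its tested members. Scores were compared between the groups by an exact permutation test over all 70 assignments of the samples, whose smallest possible two-sided p is 0.0286. Separation over all tested genes was measured as the mean distance (1 minus Pearson's r) between the groups minus that within the groups, with an exact test over 35 splits, one-sided. Relations between 6 pairs of scores were measured by Pearson's r and Spearman's rho with exact permutation p-values, adjusted over the 6.

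Genes named in the text follow a rule fixed with the tests. It took the 10 genes of largest fold change in each direction past the threshold, or, where fewer passed, those of smallest unadjusted p as values that did not pass. It also took the 4 tested members of smallest p from each list and 8 genes of interest (CD8A, CD8B, CD3E, CX3CR1, GZMB, GZMK, CCR7, PDCD1). Genes whose level can follow a donor's genotype or a single clone, and loci without a symbol, were passed over. The rule gave 116 genes, of which the text describes those of lowest p. Members of other lists named by their level alone were chosen after their values were seen. Coordinates are on GRCh38 from GENCODE release 29, which held 98.7% of the gene names.

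On simulated data with the same 9105 genes and 4 against 4 samples, the limma test recovered 6% of 50 genes changed 2-fold, 42% of those changed 4-fold, 60% of those changed 8-fold and 74% of those changed 16-fold, with 4 false calls. The changed genes were drawn from those with a mean log2(TPM + 1) of at least 3. The noise was normal and independent, with no values held at 0 and no uneven libraries. These rates may therefore not hold for lower genes or for the real libraries. In the real data the median standard error of a gene's log2 difference was 0.56 and the median 95% interval reached 1.26 to either side, or 2.39-fold. The alternatives tried were a pseudocount of 0.1 or 5, no filter, a mean TPM of at least 10, upper-quartile scaling, quantile normalization, TPM without mitochondrial and ribosomal protein genes, each sample left out in turn, and other tests for each result. Upper-quartile scaling moved the median of all tested genes in single samples by between -0.19 and 0.18 on the log2 scale. A further 3 alternatives, chosen after the data were seen, used the 4 samples with most genes above 0, the 4467 genes above 0 in all 8 samples, or the number of genes above 0 as a covariate. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.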

Results

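CD8+ T cells, the lymphocytes that kill infected and malignant cells, were profiled from the blood of patients with lung cancer (4 samples) and melanoma (4 samples). Gene levels were given as TPM for 24530 genes. The libraries were uneven. Genes above 0 numbered 9887, 17037, 18331 and 13144 in lung cancer samples 1 to 4, and 8457, 16652, 10178 and 20296 in melanoma samples 1 to 4. Of the 9105 genes tested, 24.01% were listed at 0 in lung cancer sample 1, 32.4% in melanoma sample 1 and 25.1% in melanoma sample 3, against 0.253% in melanoma sample 4. Mitochondrially encoded genes took between 20.98% and 31.8% of the TPM total, and ribosomal protein genes between 23.2% and 34.3%.

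All 8 libraries carried the transcripts of CD8+ T cells. CD8A (chromosome 2, 86784610 to 86808396), which encodes the alpha chain of the CD8 co-receptor, stood at 18.3 ± 4.15 TPM (SD, n = 4) in lung cancer and 29.7 ± 20.05 TPM (SD, n = 4) in melanoma. CD8B (chromosome 2, 86815339 to 86861924), the beta chain, stood at 10.2 ± 3.76 and 10.7 ± 3.30 TPM (SD, n = 4 each). The T cell receptor constant gene TRAC ranged from 74.3 to 615 TPM, CD3D from 59.8 to 285 TPM and CD2 from 60.1 to 400 TPM over the 8 samples. Cytotoxic genes were present beside genes of resting cells. The granzyme gene GZMA had a median of 201 TPM, the chemokine gene CCL5 355 TPM, the cytokine receptor gene IL7R 119 TPM and the lymphoid cytokine gene LTB 2029 TPM.

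Transcripts of other blood cells lay beside those of T cells. The monocyte genes S100A8 and S100A9, which encode the subunits of calprotectin, had medians of 942 and 1209 TPM and were above 0 in all 8 samples, as was LYZ (lysozyme; median 230 TPM). The B cell genes MS4A1 (CD20; median 26.6 TPM) and IGKC (an immunoglobulin light chain constant region; median 125 TPM) were above 0 in 7 samples. Melanoma sample 1 was the exception for several of these. It listed MS4A1, IGHM, IGKC, CD14 and TYROBP at 0, while it held the highest CD8A (59.1 TPM), TRAC (615 TPM) and CD2 (400 TPM). Markers of platelets, such as PF4 (63.8 to 1318 TPM), and of red cells, such as HBB (0 to 17541 TPM), varied widely. The helper T cell genes CD4 and CD40LG had medians of 2.22 and 5.35 TPM, and FOXP3 was above 0 in 2 samples at no more than 0.634 TPM.

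**Figure D1:**
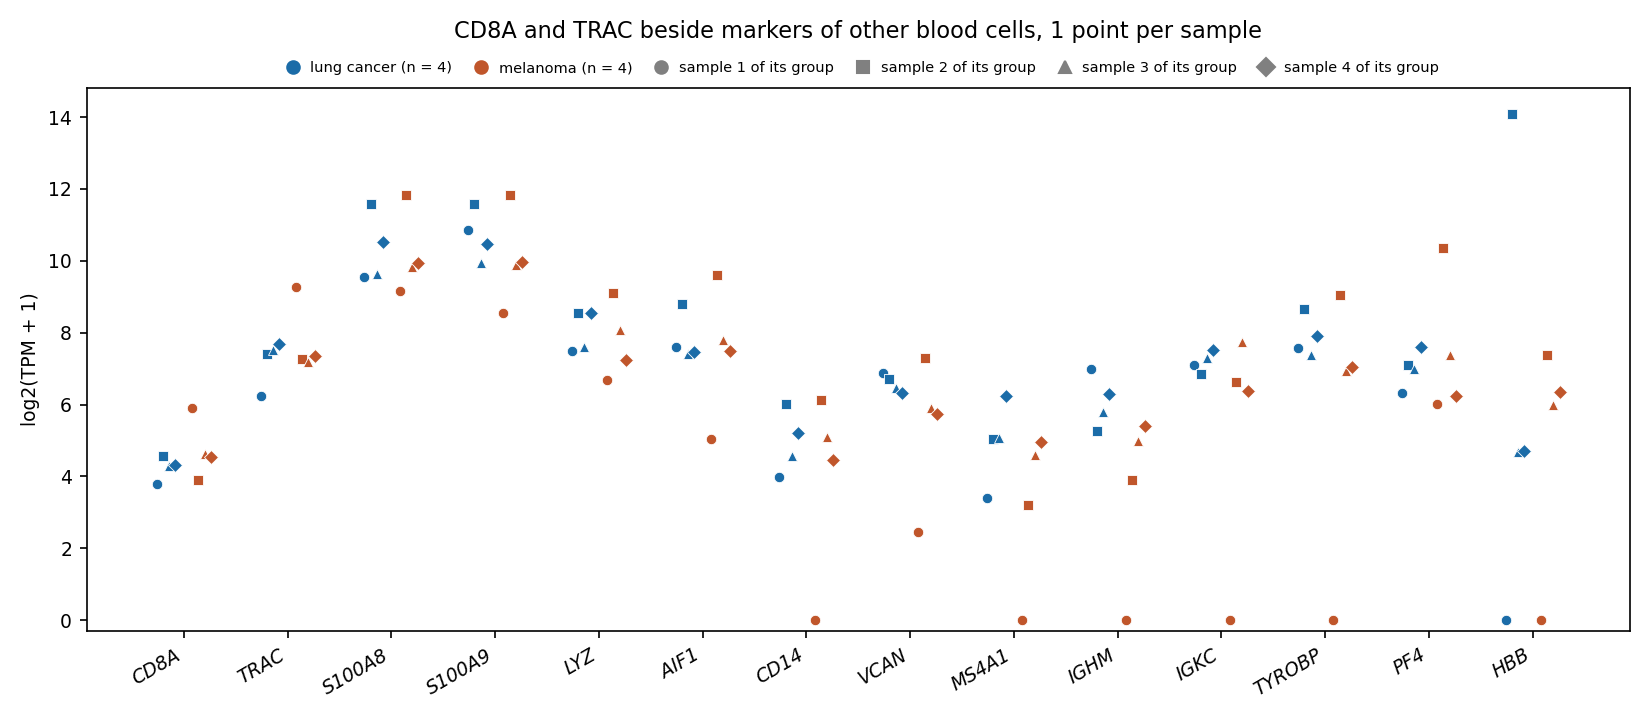
Levels of CD8A and TRAC beside monocyte (S100A8, S100A9, LYZ, AIF1, CD14, VCAN), B cell (MS4A1, IGHM, IGKC), monocyte and NK cell (TYROBP), platelet (PF4) and red cell (HBB) genes, as log2(TPM + 1) on the vertical axis, with 1 point per sample, 4 lung cancer in blue and 4 melanoma in orange. S100A8 lies above CD8A in every sample, and melanoma sample 1 sits at 0 for CD14, MS4A1, IGHM, IGKC and TYROBP.

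The series compares circulating CD8+ T cells between the cancers. No single gene passed the test, and the list member of smallest unadjusted p was LEF1 (chromosome 4, 108047545 to 108168956), a transcription factor of naive and memory precursor T cells. LEF1 stood at 20.4 ± 10.9 TPM (SD, n = 4) in lung cancer and 4.59 ± 1.71 TPM (SD, n = 4) in melanoma, a log2 difference of -1.86 ± 0.47 (SE; 95% interval -2.91 to -0.82). Its values were 35.5, 11.7, 13.1 and 21.4 TPM in the lung cancer samples and 4.95, 4.33, 2.47 and 6.62 TPM in the melanoma samples, so all 4 melanoma values lay below all 4 lung cancer values. Its limma adjusted p was 0.986 over all genes tested and 0.0355 when adjusted over the list alone (13 naive and central memory genes). The latter value was not adjusted for the number of lists.

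Of the 9105 genes, limma called 0, and 341 had an unadjusted p under 0.05 (115 higher and 226 lower in melanoma) where 455 would be expected by chance. Exact Mann-Whitney tests called 0 and gave 187 genes at an unadjusted p under 0.05. Their smallest possible p is 0.0286, so a call would need most of the 9105 genes to reach it, and the 0 says little. The 187 are the genes whose groups did not overlap, or 2.05%, where chance gives 2.86%. Without lung cancer sample 1, limma called 1 gene, the glycolytic enzyme gene PGK1, at an adjusted p of 0.0057, with adjusted p-values between 0.0057 and 1 over its alternatives. PGK1 is among the genes at 2 separate levels described below. Lung cancer sample 1 was the only lung cancer sample at its low level (1.70 TPM against 113, 90.7 and 92.4 TPM). Leaving that sample out made the levels follow the groups, so the call is not taken as a difference between the cancers.

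The 10 genes of smallest unadjusted p in each direction are values that did not pass. Among those lower in melanoma, 3 were above 0 in all samples. These were LEF1, BCL2L12, a gene of the BCL2 family (31.3 ± 4.54 against 12.9 ± 1.85 TPM, SD, n = 4 each; log2 difference -1.22 ± 0.31, SE), and RSL1D1, a nucleolar protein gene (78.7 ± 68.9 against 13.5 ± 2.75 TPM, SD, n = 4 each; log2 difference -2.06 ± 0.59, SE). The other 7 were all listed at 0 in melanoma samples 1 and 3. They were BIRC6, which encodes a ubiquitin ligase that restrains apoptosis (log2 difference -3.73 ± 0.99, SE), the small nucleolar RNA SNORD6 (-4.38 ± 1.18), the PKR activator gene PRKRA (-1.59 ± 0.39), the mitochondrial RNA methyltransferase gene MRM2 (-1.56 ± 0.43), ACBD4 (-1.55 ± 0.42), FAM209B (-1.89 ± 0.46) and FAM229A (-2.35 ± 0.62). BIRC6 stood at 149, 10.7, 23.2 and 47.6 TPM in lung cancer and at 0, 7.93, 0 and 6.41 TPM in melanoma.

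Among the 10 higher in melanoma, ZCCHC10 was above 0 in all samples, at 5.47 ± 2.45 TPM in lung cancer and 35.6 ± 27.9 TPM in melanoma (SD, n = 4 each; log2 difference 2.29 ± 0.58, SE). The other 9 were listed at 0 in lung cancer sample 1. They were SEC61G, a subunit gene of the protein channel of the endoplasmic reticulum (log2 difference 2.97 ± 0.81, SE), the transcription factor gene ASCL2 (2.06 ± 0.66), the kinase gene DAPK3 (1.46 ± 0.49), the small GTPase gene RHEBL1 (1.95 ± 0.66), the nucleotide hydrolase gene NUDT2 (2.37 ± 0.80), the peroxisomal membrane protein gene PXMP2 (1.99 ± 0.67), GLMN (2.41 ± 0.74), TMEM141 (2.34 ± 0.57) and RPS26P6 (2.66 ± 0.58). RPS26P6 is a processed pseudogene of RPS26, and whether its reads came from RPS26 was not tested.

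Genes of naive and central memory cells were lower in melanoma for 9 of 13 tested members, and the list did not pass (camera adjusted p = 0.403). Its score was 4.56 ± 0.187 in lung cancer and 4.26 ± 0.215 in melanoma (SD, n = 4 each; exact permutation p = 0.114, adjusted p = 0.943). With upper-quartile scaling the exact permutation p was 0.0286, the smallest possible (adjusted p = 0.60), and with quantile normalization it was 0.0571. Apart from LEF1, FOXP1, which holds T cells in quiescence, had a log2 difference of -1.48 ± 0.76 (SE). FOXP1 stood at 3.12 and 4.35 TPM in melanoma samples 1 and 3 and at 19.4 to 57.9 TPM in the other 6. CCR7, the lymph node homing receptor gene, averaged 44.2 ± 10.99 TPM in lung cancer and 49.2 ± 31.0 TPM in melanoma (SD, n = 4 each), with a 95% interval of -0.97 to 0.97 for the log2 difference.

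Genes of cytotoxic effector cells were higher in melanoma for 15 of 22 tested members, and the list did not pass (camera adjusted p = 0.193). The score was 3.42 in lung cancer sample 1, 4.05 to 4.28 in the other lung cancer samples and 3.77 to 4.55 in melanoma. Lung cancer sample 1 thus lowered the mean of its group. The granzyme gene GZMB stood at 19.8 ± 10.2 TPM in lung cancer and 32.4 ± 13.6 TPM in melanoma (SD, n = 4 each; log2 difference 0.78 ± 0.49, SE). CX3CR1, the fractalkine receptor gene of circulating effector cells, stood at 12.5 ± 8.84 and 22.2 ± 12.3 TPM (log2 difference 0.90 ± 0.61, SE), and S1PR5 at 4.64 ± 2.89 and 8.93 ± 3.37 TPM (0.89 ± 0.50, SE). ZEB2, a transcription factor gene of terminal effector cells, went the other way, at 10.8 ± 2.85 and 5.64 ± 3.06 TPM (-0.98 ± 0.52, SE). CX3CR1 and GZMB were lowest in lung cancer sample 1, at 3.21 and 7.2 TPM. Over the alternatives the log2 differences ran from 0.43 to 1.29 (CX3CR1), 0.39 to 1.03 (GZMB), 0.54 to 1.56 (S1PR5) and -1.19 to -0.35 (ZEB2). Melanoma sample 1 had the lowest monocyte and B cell scores and the fewest genes above 0, and it listed GZMH and PRF1 at 0. Without melanoma sample 1, the cytotoxic list reached an adjusted camera p of 0.0437 (adjusted p = 0.774 with an estimated correlation). In the 4 samples with most genes above 0, the cytotoxic effector list reached an adjusted camera p of 0.0194 (adjusted p = 0.738 with an estimated correlation). NK cell markers were also present (medians of 12.8 TPM for KLRF1 and 13.4 TPM for NCR1). How far cells other than CD8+ T cells contributed to the cytotoxic genes, CX3CR1 among them, was not tested.

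In the GZMK effector memory list, 8 of 12 tested members were higher in melanoma (camera adjusted p = 0.21). The list score was 3.32 in lung cancer sample 1, 3.90 to 4.55 in the other lung cancer samples and 4.05 to 4.91 in melanoma. GZMK itself stood at 83.3 ± 19.3 and 106 ± 46.1 TPM (SD, n = 4 each; log2 difference 0.27 ± 0.39, SE), SLAMF7 had a log2 difference of 0.60 ± 0.40 (SE), and the chemokine receptor gene CXCR3 one of 1.37 ± 0.91 (SE). CXCR3 was listed at 0 in lung cancer sample 1 and stood at 41.4 TPM in melanoma sample 1. Its log2 difference ran from 0.29 to 2.19 over the alternatives. Of the T cell receptor complex and CD8 genes, 8 of 12 were higher in melanoma (camera adjusted p = 0.193). Their score was 5.24 in melanoma sample 1, 4.40 to 4.87 in the other melanoma samples and 4.26 to 4.75 in lung cancer. CD3D stood at 89.8 ± 29.7 and 178 ± 73.3 TPM (log2 difference 0.96 ± 0.37, SE) and CD3E at 24.1 ± 1.67 and 36.1 ± 12.5 TPM (0.51 ± 0.34, SE). CD3E was highest in melanoma sample 1, at 52.7 TPM. Over the alternatives the log2 differences ran from 0.56 to 1.15 (CD3D) and 0.23 to 0.67 (CD3E).

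Checkpoint receptor genes were listed at 0 in many libraries, which does not show that they were absent, since 3 libraries also list housekeeping genes at 0. PDCD1, which encodes PD-1, was above 0 in 4 samples, at 5.48 and 0.615 TPM in lung cancer samples 1 and 2 and at 5.84 and 12.9 TPM in melanoma samples 1 and 2, and did not meet the filter for testing. CTLA4 was above 0 in 3 samples and LAG3 in 4, and TIGIT ranged from 1.86 to 10.2 TPM. Of the 7 tested members of the checkpoint and exhaustion list, 3 were higher and 4 lower in melanoma (camera adjusted p = 0.703). Their median log2 difference was -0.26, while the mean difference in score was 0.01 and camera pointed upward. The transcription factor gene BATF stood at 15.9 ± 4.12 TPM in lung cancer and 43.8 ± 29.6 TPM in melanoma (SD, n = 4 each; log2 difference 1.18 ± 0.51, SE), with 79.9 and 55.8 TPM in melanoma samples 1 and 3. HAVCR2, which encodes TIM-3, had a log2 difference of -0.73 ± 0.50 (SE) and was listed at 0 in melanoma samples 1 and 3.

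**Figure D2:**
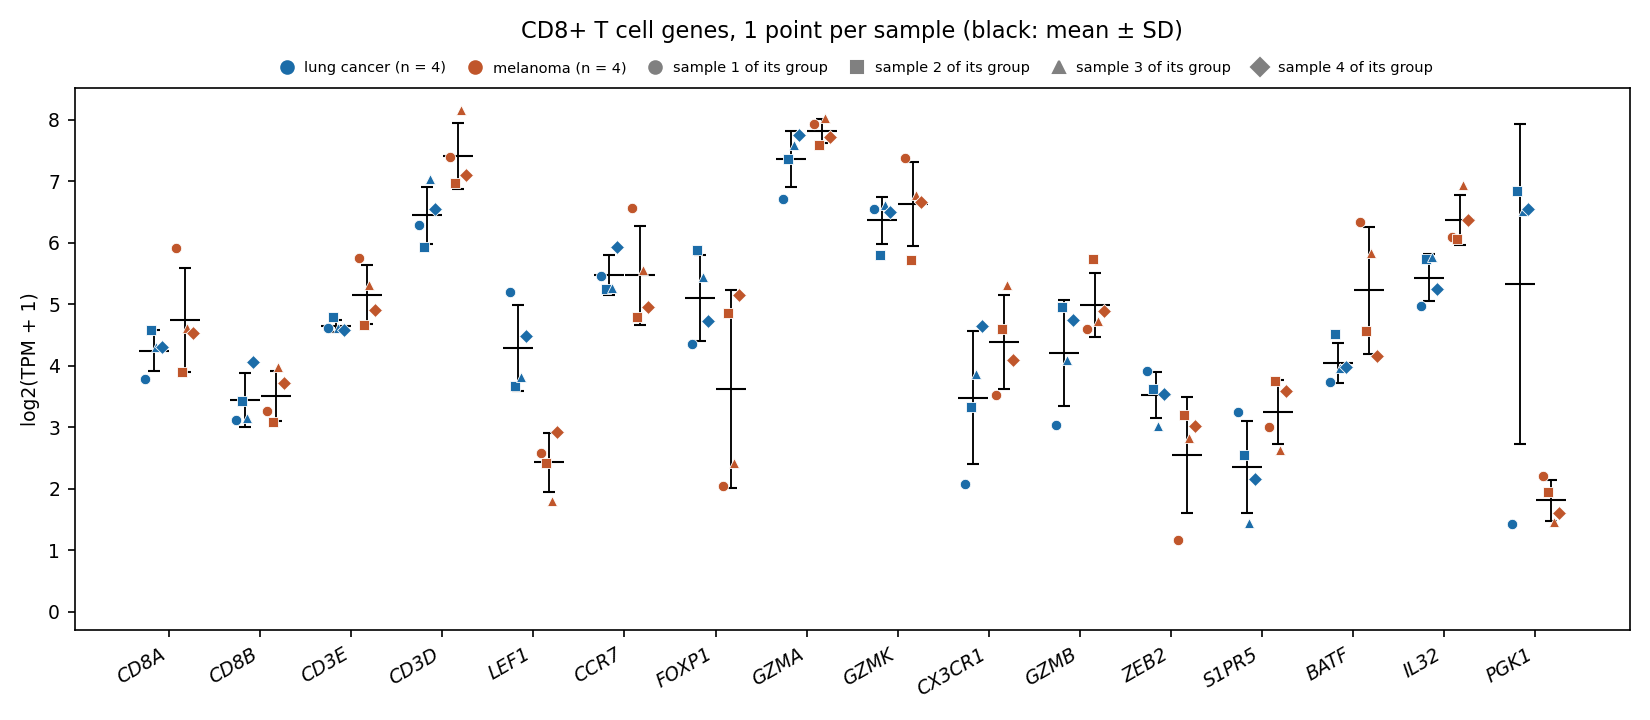
Levels of 16 T cell genes as log2(TPM + 1) on the vertical axis, with 1 point per sample, 4 lung cancer in blue and 4 melanoma in orange, and the mean ± SD of each group in black. The LEF1 points of melanoma lie below those of lung cancer, and the PGK1 points of lung cancer samples 2 to 4 stand apart from the other 5.

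Immediate early and activation genes, which respond within minutes to stimulation or handling, were lower in melanoma for 17 of 20 tested members (camera adjusted p = 0.193). JUND had a log2 difference of -1.22 ± 0.63 (SE) and FOSB one of -1.02 ± 0.64 (SE). The score was 2.69 in melanoma sample 1 and between 4.26 and 5.34 in the other 7 samples, and the monocyte score was likewise lowest in melanoma sample 1. Without melanoma sample 1, the difference in the immediate early score was 0.02. Without melanoma sample 2, the list reached an adjusted camera p of 0.00104 (adjusted p = 0.804 with an estimated correlation).

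Of the HLA class II and activation surface genes, 4 of 6 tested members were lower in melanoma (camera adjusted p = 0.533). The invariant chain gene CD74 stood at 100.8 ± 23.5 and 66.2 ± 14.8 TPM (SD, n = 4 each; log2 difference -0.60 ± 0.31, SE), and HLA-DMB had a log2 difference of -1.51 ± 0.70 (SE). These genes are also expressed by B cells and monocytes, whose lists were lower in melanoma for 7 of 7 and 12 of 13 tested members. Among cytokine and chemokine genes, 5 of 9 were higher (camera adjusted p = 0.606), with a difference in score of -0.02 although camera pointed upward. IL32, an inflammatory cytokine gene of activated lymphocytes, was higher in all 4 melanoma samples (84.1 ± 26.3 TPM) than in any lung cancer sample (43.3 ± 11.4 TPM; SD, n = 4 each; log2 difference 0.93 ± 0.34, SE; limma adjusted p = 0.986), and XCL1 had a log2 difference of 1.32 ± 0.81 (SE).

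Type I interferon response genes divided evenly, with 8 of 16 higher in melanoma (camera adjusted p = 0.572). Their median log2 difference was -0.12, while the difference in score was 0.12 and camera pointed upward. IFI44 and EPSTI1 had log2 differences of 1.79 ± 0.69 and 1.55 ± 0.66 (SE), and both were listed at 0 in lung cancer sample 1. Proliferation genes were higher in melanoma for 9 of 10 tested members (camera adjusted p = 0.193), with STMN1 at a log2 difference of 0.89 ± 0.61 (SE) and the replication clamp gene PCNA at -1.02 ± 0.76 (SE). TOP2A, a topoisomerase gene of dividing cells, stood at 64.9 TPM in melanoma sample 1 and at no more than 6.57 TPM in the other 7. The proliferation score was 4.14 in melanoma sample 1 and between 2.13 and 2.91 in the other 7 samples. Without melanoma sample 1, the difference in score went from 0.27 to -0.21.

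Tissue residency genes were lower for 5 of 6 tested members (camera adjusted p = 0.703), with log2 differences of -0.39 ± 0.54 for ITGAE and -0.63 ± 0.89 for PRDM1 (SE). The score was 3.67 in lung cancer sample 3, 2.89 to 3.02 in the other lung cancer samples and 2.65 to 3.10 in melanoma. ITGAE and PRDM1 were highest in lung cancer sample 3, at 4.73 and 27.2 TPM. Over the alternatives the log2 difference of ITGAE ran from -0.98 to -0.01. Genes of MAIT and innate-like T cells were higher for 3 of 6 (camera adjusted p = 0.298). Their score was 1.31 in lung cancer sample 1, 2.77 to 3.84 in the other lung cancer samples and 1.98 to 4.22 in melanoma. KLRB1, which encodes CD161, had a log2 difference of 2.13 ± 1.04 (SE) and was listed at 0 in lung cancer sample 1. Without melanoma sample 3, the MAIT list reached an adjusted camera p of 0.0191 (adjusted p = 0.774 with an estimated correlation), and in the 4 samples with most genes above 0 one of 0.0194 (adjusted p = 0.738 with an estimated correlation). NK cell markers divided evenly, with 4 of 8 higher in melanoma (camera adjusted p = 0.677, pointing upward against a median of -0.07 and a difference in score of -0.03) and a log2 difference of 1.91 ± 0.76 (SE) for KLRF1 and of 0.74 ± 0.55 (SE) for NCR1.

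Housekeeping programs differed little in score. Oxidative phosphorylation genes were higher in melanoma for 13 of 21 members (camera adjusted p = 0.298), with log2 differences of 0.56 ± 0.34 for NDUFB2 and 0.47 ± 0.28 for NDUFA1 (SE). Cytosolic ribosomal protein genes were lower for 14 of 24 (camera adjusted p = 0.896), with RPL19 at 0.71 ± 0.27 and RPS14 at -0.48 ± 0.27 (SE). Mitochondrially encoded genes were lower for 10 of 13 (camera adjusted p = 0.634), with MT-ATP8 at -0.49 ± 0.27 and MT-ND2 at -0.53 ± 0.34 (SE). Heat shock genes divided evenly, with 5 of 10 higher (camera adjusted p = 0.896), HSPE1 at -0.95 ± 0.72 and HSPH1 at -0.37 ± 0.44 (SE).

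Glycolysis genes were lower in melanoma for 10 of 14 tested members (camera adjusted p = 0.896). PGK1 (chromosome X, 77910739 to 78129296) stood at 113, 90.7 and 92.4 TPM in lung cancer samples 2, 3 and 4, at 1.70 TPM in lung cancer sample 1, and between 1.76 and 3.63 TPM in the 4 melanoma samples (log2 difference -3.52 ± 1.09, SE). It is among the genes at 2 separate levels described below. The glucose transporter gene SLC2A1 stood at 52.3 and 38.1 TPM in melanoma samples 1 and 3 and at no more than 3.80 TPM in the other 6 (log2 difference 2.62 ± 1.09, SE).

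B cell markers were lower in melanoma for 7 of 7 tested members (camera p = 0.00321, adjusted p = 0.0675; adjusted p = 0.847 with an estimated correlation). IGHM had a log2 difference of -2.51 ± 1.06 and MS4A1 one of -1.74 ± 1.05 (SE). The score was 3.95 ± 0.265 in lung cancer and 2.62 ± 1.80 in melanoma (SD, n = 4 each; exact permutation p = 0.143). It was 0 in melanoma sample 1, and without that sample the difference went from -1.33 to -0.45 (exact permutation p = 0.229). The list passed under 5 changes of the processing and without melanoma sample 3 or 4, with adjusted camera p-values between 0.00266 and 0.0306, and in none of these with an estimated correlation (adjusted p between 0.701 and 0.891).

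Monocyte markers were lower in melanoma for 12 of 13 tested members (camera adjusted p = 0.193), with VCAN at -1.24 ± 0.86 and MS4A6A at -1.06 ± 0.74 (SE). The monocyte score was 3.28 in melanoma sample 1 and 6.71 in melanoma sample 2, and between 5.12 and 6.35 in the other 6. Without melanoma sample 2 the list reached an adjusted camera p of 0.00066 (adjusted p = 0.804 with an estimated correlation), and without melanoma sample 1 the difference in score went from -0.61 to 0.02. Platelet markers were higher for 4 of 7 (camera adjusted p = 0.648), with TUBB1 at 0.74 ± 1.02 and GNG11 at 0.56 ± 0.93 (SE). The platelet score was 5.80 in melanoma sample 2 and at most 3.54 in the other 7.

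Lists with fewer than 4 tested members were described by their values. CD4 had a log2 difference of -1.12 ± 0.55 and IKZF2 one of 0.46 ± 0.37 (SE). The neutrophil genes FCGR3B (at most 2.83 TPM) and CSF3R (at most 5.14 TPM) had log2 differences of -0.21 ± 0.58 and -0.23 ± 0.69 (SE). The globin genes HBA1 and HBA2 had log2 differences of -3.04 ± 1.52 and -1.51 ± 1.88 (SE), with 609 and 2266 TPM in lung cancer sample 2. The plasmacytoid dendritic cell gene LILRA4 reached at most 2.44 TPM. The melanocyte genes MLANA and PMEL reached at most 0.602 and 2.50 TPM, and no lung epithelial marker in the table exceeded 0.38 TPM.

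**Figure D3:**
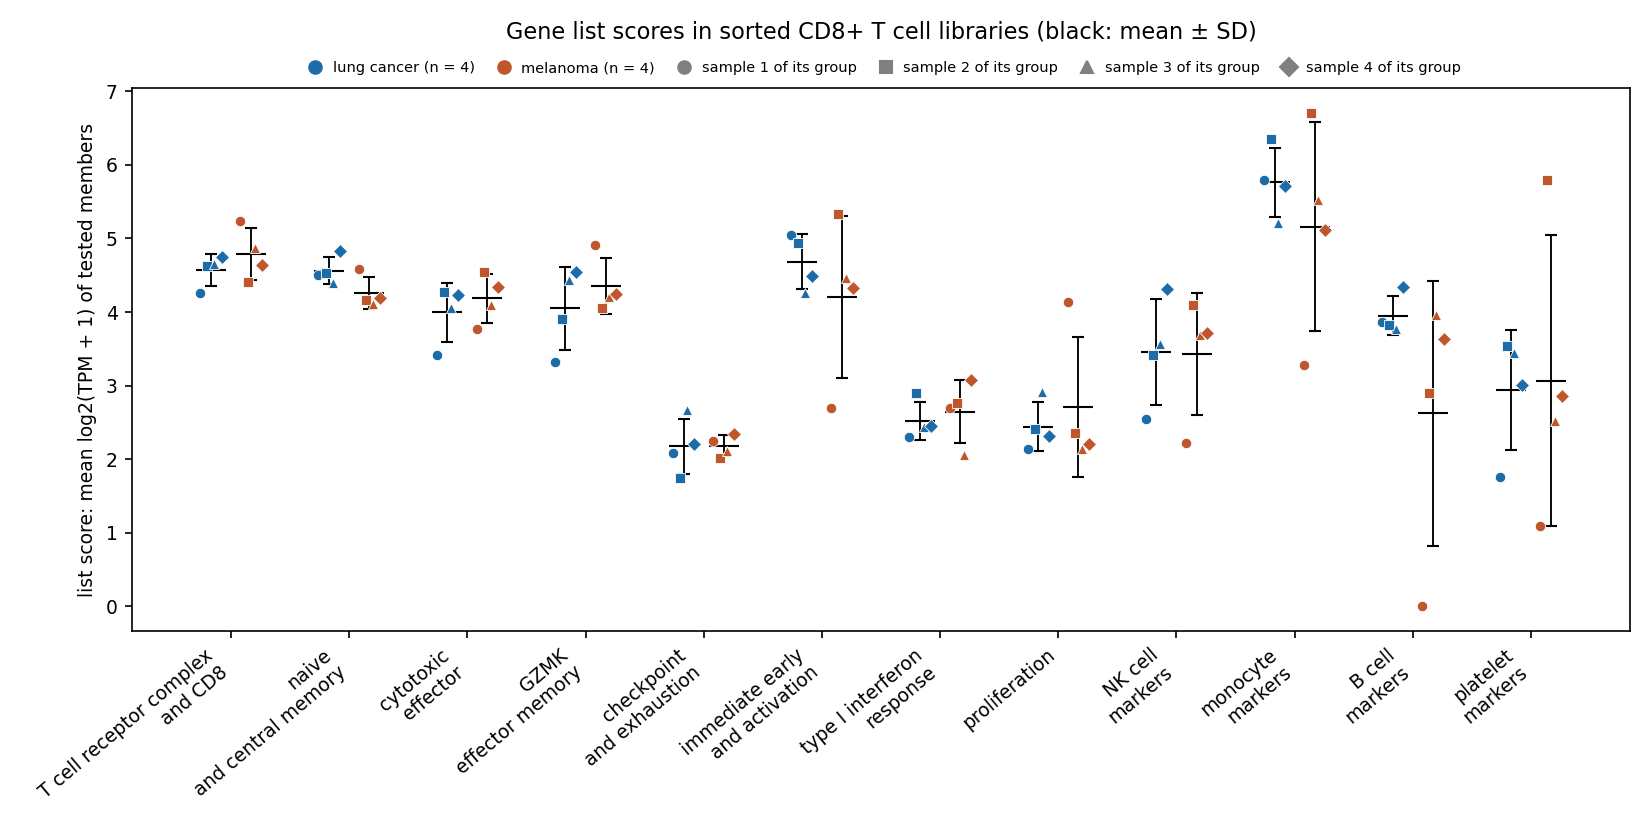
Scores of 12 gene lists (mean log2(TPM + 1) of the tested members, vertical axis) in each sample, 4 lung cancer in blue and 4 melanoma in orange, with the mean ± SD of each group in black. The groups overlap for every list drawn, and melanoma sample 1 sits apart in the B cell (0), monocyte (3.28), immediate early (2.69) and proliferation (4.14) scores.

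Over the 21 lists tested, camera with the preset correlation called 0, with 4 at an unadjusted p under 0.05. With an estimated correlation 0 were called and 0 had an unadjusted p under 0.05, and the same counts held for fry in a shared direction and in either direction. Exact permutation tests of the scores gave 0 lists with an adjusted p under 0.05 and 0 with an unadjusted p under 0.05, and the smallest p was 0.114. With a smallest possible p of 0.0286, an adjusted p under 0.05 would need most of the 21 lists to reach it. The 0 after adjustment therefore says little. Adjusted over the list alone, LEF1 was the only gene of the 27 lists to pass. With no adjustment across the lists, such a pass can arise by chance.

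Over all tested genes, the groups did not separate. The mean distance between samples of different groups was 0.222 and that between samples of the same group 0.226, a difference of -0.0035 (exact permutation p = 0.571 over 35 splits, one-sided). It was 0.0184 without melanoma sample 2 and 0.0194 without melanoma sample 4.

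The scores of CD8+ T cell states were also followed across the 8 samples, over 6 relations in the same family. These libraries also held transcripts of other blood cells, and how far such cells contributed to the scores was not tested. CX3CR1 and the cytotoxic effector score (CX3CR1 left out) had the largest Pearson's r (r = 0.62, exact permutation p = 0.09998, adjusted p = 0.60; rho = 0.36, exact p = 0.389, adjusted p = 0.793). Without the 2 samples farthest from the median of CX3CR1, r was 0.50, and after each group was centred on its mean it was 0.59. Without lung cancer sample 1 alone, r was 0.15. CX3CR1 and the naive score gave r = -0.37 (exact p = 0.367, adjusted p = 0.676) and rho = -0.40 (exact p = 0.327), and r was -0.07 without the 2 farthest samples and -0.08 within groups. It was -0.82 without lung cancer sample 4 (exact p = 0.0127, adjusted p = 0.0762) and -0.12 without melanoma sample 3. The cytotoxic and naive scores gave r = -0.34 (exact p = 0.417, adjusted p = 0.676) and rho = -0.33 (exact p = 0.428), with r = -0.18 without the 2 farthest samples and -0.20 within groups. Over the settings of the processing, r of this pair ran from -0.72 for genes above 0 in all 8 samples to 0.29 without mitochondrial and ribosomal protein genes.

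The cytotoxic and GZMK effector memory scores gave r = 0.25 (exact p = 0.546, adjusted p = 0.676) and rho = -0.12 (exact p = 0.793). Without the 2 samples farthest from the median, r was -0.48, and within groups it was 0.17. It was -0.77 without lung cancer sample 1 and 0.63 without melanoma sample 1. The cytotoxic and checkpoint scores gave r = -0.13 (exact p = 0.753, adjusted p = 0.753) and rho = -0.26 (exact p = 0.536), with r = -0.47 without the 2 farthest samples and -0.14 within groups. The naive and immediate early scores gave r = -0.26 (exact p = 0.563, adjusted p = 0.676) and rho = -0.17 (exact p = 0.703), with r = -0.44 and -0.65 in those settings. None of the 6 relations passed after adjustment.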

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

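All tests against other splits of the samples, the correlation of the monocyte markers and the test for gene copies were chosen only after the results they bear on had been seen. Of 58 groups of 4 values examined (list scores, measures of the libraries and globin genes, a choice also made after the data were seen), 7 held a sample far from the other 3, where chance gives about 1 in 20, or 2.9. That rate holds for independent, normally distributed values. Of the 7, 3 are globin genes in the same library, and list scores are related, so the excess is not a test.

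The proliferation score of melanoma sample 1 was 4.14 and those of the other melanoma samples lay between 2.13 and 2.36. The cytokine and chemokine score of lung cancer sample 1 was 1.68 and those of the other lung cancer samples lay between 3.15 and 3.18. Lung cancer sample 1 listed the members IFNG, CCL3, XCL1, XCL2 and FASLG at 0, as it did 24.01% of all tested genes. Lung cancer sample 2 held 17541 TPM of HBB, 2266 TPM of HBA2 and 609 TPM of HBA1, each far above the other lung cancer samples. The listed TPM summed to 566242 in lung cancer sample 3 and to 545804 in melanoma sample 4, below the other samples of their groups, and these samples listed the most genes in their groups.

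The comparison of melanoma with lung cancer was set against the other ways to divide the 8 samples into 4 and 4. All 35 splits gave at least as many genes past the threshold as the real one, which gave 0 (highest other 181). For genes with an unadjusted p under 0.05, 20 of the 35 splits gave as many as the 341 of the real one (highest other 897), and for lists past the camera threshold 35 of 35 gave as many as its 0 (highest other 8). Chance can thus not be excluded for the count at an unadjusted p under 0.05, while for the other counts a real value of 0 is reached by every split whatever the data, so those comparisons carry no information.

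The split with 181 genes points to a structure of the samples. It set the 4 samples with the fewest genes above 0 (lung cancer samples 1 and 4, melanoma samples 1 and 3) against the other 4, and the remaining splits called at most 4 genes. Of the 181 genes, 167 were lower in those 4 samples, and 81.8% were listed at 0 in at least 1 of them, against 50.8% of all tested genes. Among the 4467 genes above 0 in all 8 samples, the split called 22, or 0.493%, but a gene that is lower in those 4 samples is also more often listed at 0, so this selection cannot separate fewer reads from a difference between the cells. Genes with an unadjusted p under 0.05 were 695 of these 4467 and 897 of all 9105, while the genes past the threshold lay mostly among those listed at 0, and the source of the difference was left open.

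Monocyte transcripts in libraries of sorted CD8+ T cells are the second pattern. Division by transcript length raises the short S100A8 transcript against CD8A, but after TPM was multiplied by the longest annotated transcript the median ratio of S100A8 to CD8A was still 12.1, and it was above 3 in 7 of 8 samples, which argues against length as the whole cause. The 13 tested monocyte markers had a median pairwise correlation of 0.769 over the 8 samples, above 100% of 10000 random lists of matched expression (median 0.01), and of 0.63 without melanoma sample 1. RNA from monocytes may therefore have entered the libraries, although a sort on CD8 would remove such cells, and free RNA or uptake by T cells was not tested. The disease groups were not separated by this score (exact permutation p = 0.543).

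Genes at 2 separate levels are the third pattern. Among 1309 genes above 0 in all samples with a mean of at least 20 TPM, 8 fell into levels at least 4-fold apart with at most a 2-fold range within each, and 30 with at most a 4-fold range, PGK1 and FOXP1 among them. None of the 30 divided the samples by disease. PSMC1, RRP15, MCTS1 and USP48 were high in lung cancer samples 2 and 3 and melanoma samples 2 and 4. That is the division into the 4 samples with most genes above 0 and the other 4. PGK1 and FOXP1 divided the samples otherwise, and a link of the levels to the number of reads was not tested. The 8 genes had a median log2 ratio of longest to shortest annotated transcript of 3.24 against 1.68 in matched random lists (above 97.9% of them), and the 30 had 3.32 (above 99.99%), which is consistent with transcripts of different length being assigned in different libraries for part of them, but 5 of the 30, and 1 of the 8, have a single annotated length that cannot give 2 levels in this way, among them the gene copies EEF1A1P5, EEF1A1P13, RPL41P1 and RPS28P7. Pseudogenes or genes with an annotated pseudogene made up 62.5% of the 8 against 37.5% in matched lists and 36.7% of the 30 against 36.7%, so shared reads of gene copies were left open, and a biological explanation was not tested.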

How the results depend on the processing

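The alternatives that used the 4 samples with most genes above 0, the genes above 0 in all 8 samples, or the number of genes above 0 as a covariate were chosen after the data were seen. Of 73 named genes followed through the alternatives, 65 kept their direction in all and 8 turned in some, and over all runs 1257 of 1274 kept direction and side of the threshold. LEF1 kept its direction, with log2 differences between -2.07 and -1.21. Its groups did not overlap, so leaving out a sample or changing the pseudocount could not turn it. Most of the 73 genes were chosen by smallest p in the same data, so these counts are no separate evidence for a difference. Of 21 list scores, 10 kept their direction in all alternatives and 11 turned in some. No gene passed in any setting with all 8 samples. The count of genes with an unadjusted p under 0.05 was 72 at a mean TPM of at least 10 (2659 genes tested), 134 for genes above 0 in all 8 samples (4467 tested) and 187 by exact Mann-Whitney tests, against 341. With quantile normalization 154 such genes were higher and 147 lower, against 115 and 226. The number of lists past the threshold was 1 with a pseudocount of 5, 1 with no filter, 1 at a mean TPM of at least 10, 1 with quantile normalization, 1 without mitochondrial and ribosomal protein genes, and 2 in the 4 samples with most genes above 0, against 0. In those 4 samples the distance was -0.0052 (exact permutation p = 1 over 3 splits), and the exact tests of scores, over 6 assignments, cannot reach 0.05. The exact permutation p of the naive score was 0.0286 with upper-quartile scaling and without melanoma sample 1, and that value was also reached by the B cell score without melanoma sample 3 and by the glycolysis score for genes above 0 in all 8 samples, none past the threshold after adjustment.

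With a pseudocount of 0.1, the relation of the cytotoxic with the naive score was r = 0.24 and with the checkpoint score r = 0.40, and the differences in score were -0.26 for checkpoint, -0.07 for interferon and -0.17 for platelet genes. With a pseudocount of 5 they were 0.09 for cytokines and 0.01 for CCR7. With no filter the cytotoxic and checkpoint scores gave r = 0.18. With upper-quartile scaling the cytotoxic score gave r = 0.04 with the naive and 0.23 with the checkpoint score, the naive and immediate early scores gave 0.06, and the oxidative phosphorylation score differed by -0.01. With quantile normalization the differences in score were 0.09 for cytokines, -0.01 for oxidative phosphorylation, 0.01 for ribosomal proteins and 0.03 for NK cells. Without mitochondrial and ribosomal protein genes the cytotoxic score gave r = 0.29 with the naive and 0.52 with the checkpoint score, CX3CR1 gave 0.03 with the naive score, and the differences were 0.01 for the NK score and 0.04 for CCR7. With z-scores they were 0.12 for cytokines and 0.06 for NK cells, and with array weights 0.04 for HAVCR2. The cytotoxic and GZMK scores gave r = -0.48 without the 2 samples farthest from the median and -0.03 for genes above 0 in all 8 samples. The relation of the cytotoxic with the naive score was closer in other settings, at r = -0.69 with a pseudocount of 5, -0.71 at a mean TPM of at least 10 and -0.72 for genes above 0 in all 8 samples, none past the threshold after adjustment. For all of these, the cause was not tested.

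With 1 sample left out at a time, the genes called ranged from 0 to 1 and the lists from 0 to 2. The distance ranged from -0.0205 to 0.0194, r of the cytotoxic with the GZMK score from -0.77 to 0.63, and r of the cytotoxic with the checkpoint score from -0.38 to 0.01. For the other relations r ranged from -0.62 to -0.16 (cytotoxic with naive), -0.37 to -0.04 (naive with immediate early), 0.15 to 0.81 (CX3CR1 with cytotoxic) and -0.82 to -0.12 (CX3CR1 with naive), none past the threshold after adjustment. Differences in score ranged from -0.14 to 0.17 (checkpoint), -0.86 to 0.02 (immediate early), -0.39 to 0.19 (cytokines), -0.02 to 0.32 (interferon), -0.21 to 0.46 (proliferation), -0.09 to 0.12 (oxidative phosphorylation), -0.17 to 0.02 (ribosomal proteins), -0.22 to 0.02 (mitochondrially encoded), -0.33 to 0.37 (NK cells), -1.12 to 0.02 (monocytes) and -0.78 to 0.79 (platelets). Log2 differences ranged from -1.06 to 0.29 (PRDM1), -0.63 to 0.13 (FCGR3B), -0.74 to 0.20 (CSF3R), -0.31 to 1.04 (GNG11), -2.40 to 0.35 (HBA2), -0.08 to 0.28 (CD8B) and -0.37 to 0.22 (CCR7). The cause was not tested. Values of 0 limit the genes that can be compared, since 50.9% of the tested genes were listed at 0 in at least 1 sample, and how much of this is due to depth was not measured.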

Other observations

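Monocyte and T cell transcripts were set against each other after the data were seen. The monocyte score and the T cell receptor and CD8 score gave r = -0.79 over the 8 samples (exact permutation p = 0.0277) and rho = -0.71 (exact permutation p = 0.0576), and r = -0.19 (exact permutation p = 0.722) and rho = -0.43 (exact permutation p = 0.419) without the 2 samples farthest from the median monocyte score. Calprotectin genes were highest in melanoma sample 2, at 3654 TPM for S100A8 and 3658 TPM for S100A9, and lowest in melanoma sample 1, at 573 and 373 TPM.

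The gamma and delta T cell receptor constant genes were present in these CD8+ T cell libraries. TRGC2 ranged from 14.2 to 81.8 TPM and TRGC1 from 5.25 to 21.5 TPM, both above 0 in all 8 samples, while TRDC was above 0 in 6 and reached 55.6 TPM in melanoma sample 1. Mitochondrial and ribosomal transcripts were among the highest in TPM, with medians of 35350 TPM for MT-ND3 and 13860 TPM for RPS12. Division by length raises short genes such as MT-ND3 (mitochondrial positions 10059 to 10404), so TPM does not rank genes by number of molecules here. The longer MT-ND1 and MT-CO1 had medians of 3275 and 1088 TPM. The mitochondrial transfer RNA gene MT-TF took 8.35% of the TPM total in melanoma sample 2 and between 0.926% and 3.17% in the other samples.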
